A study of Homo sapiens with 8 samples.

How the data were processed

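Total RNA of 8 cell lines was extracted with a Qiagen RNeasy Mini kit and made into libraries with Illumina's TruSeq RNA kit, per the labels' protocols. Reads were aligned with BWA 0.6.2 to hg19, per the submitters' processing notes. The fusion caller, its filters and the sequencing depth are not given in the sources used here. The deposited list holds 1 row per fusion junction, with counts of discordant read pairs and of split reads, per the file headers. These counts are not scaled to library size. The same deposited list gives, as text, the partners in transcript order, the class of the pair, the boundary exon of each gene with its RefSeq transcript, and a template sequence with the junction marked.

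The lowest count of discordant pairs was 3 and of split reads 1, so the list holds junctions above some minimum, and a pair that is not listed may be present at a lower level. Pairs with few reads in a shallow library can go unlisted, which limits every comparison of pair numbers between lines. Count models for genes did not apply: the list has no zeros, no gene totals and 1 library per line. Exon starts count from 0 in the list, since template lengths equalled exon lengths on that reading in 95 of 96 junctions; all positions are given from 1. The listed class matched the chromosomes in 96 of 96 junctions.

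Junctions were collapsed to unordered gene pairs per line. A pair took the highest sum of discordant pairs and split reads over its junctions, and 10 pairs had more than 1 junction. Discordant pairs were equal over the junctions of a pair in 10 of these 10, so they look counted per gene pair, and a sum over junctions counts them again. Same-chromosome pairs were called nearby when their nearest junctions were at most 200 kb apart. Lines were grouped by their label as 7 cancer lines and 1 normal line. Pair numbers were compared by an exact permutation test. Shares have exact Clopper-Pearson 95% intervals and were compared between lines by 100000 permutations of the class over pairs with a chi-square statistic, and between groups by Fisher's exact test. Reads by class were compared as mean log2 reads with 100000 permutations of the class within lines, two-sided. Partner ends were compared for every line and chromosome with at least 5 ends by Fisher's exact test, and gene lists between pair classes likewise, with Benjamini-Hochberg adjustment and a threshold of 0.05. No batch was given in the labels. These tests, the alternatives, 47 known fusions and 8 gene lists were fixed before the data were examined. Afterwards the ribosomal pattern of the high-abundance list was narrowed, because it also matched the kinase gene RPS6KB1. The rule for named genes took the 3 pairs with most reads per line, each known fusion found, up to 10 pairs in at least 2 lines and the 5 genes with most partners.

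Genes of the list were matched to GENCODE 29 by current or older symbol or RefSeq transcript, for 150 of 150 genes. That annotation is on another build, so it gave only transcript sequences, coding regions and names. The 25 bases on each side of a junction were placed on the partners' transcripts, which put both genes in sense in 94 of 96 templates, 49 as listed and 45 as the reverse complement. A join was called in frame when coding phases matched. The 40 bases around each junction were searched in all transcripts, and a side was called repeated when more than 10 genes held its 25 bases. The 60 bases around each junction were also aligned to each partner's transcripts to count edits.

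The alternatives used junctions with at least the list's median of 14.5 supporting reads, no high-abundance genes, each junction counted, no pairs of the normal line or several lines, distances of 100 kb or 1 Mb, medians, sums over junctions, ordered pairs, identical junctions, and each line left out of the interchromosomal share and the read differences. Added after seeing the data were the comparison of nearby pairs by order with its alternatives, pairs without a repeated side, pairs without an annotated joined sequence, overlapping partner names merged, discordant pairs or split reads alone, pairs counted per chromosome, each line left out of the share of nearby pairs, and MDA-MB-231 left out. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, edlib 1.3.9 and matplotlib 3.10.9 were used. The tests were tried on 200 simulated lists of 86 pairs each. With 50% of the ends of BT-474 set to chromosome 17, besides those drawn there, 91.5% of lists called it and 14.5% made another call. With no such excess 2.5% made a call. The 2 ends of a simulated pair were drawn independently, whereas 70 of the 86 listed pairs had both on 1 chromosome. These rates therefore need not hold for the test of ends in the list. A log2 shift of -1 in reads was called in 51.5% of lists, -2 in 99.5% and 0 in 4.5%. An adjacent share of 0 in BT-474 was called in 94% and equal shares in 7%. Of 195 made-up joins of coding transcripts, 100% were read in the right orientation and frame.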

Results

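The series asked which fusion transcripts, RNAs that join exons of different genes, breast cancer cell lines express. RNA was sequenced from 7 breast cancer cell lines and from MCF10A, an immortalised breast epithelial line that the labels call normal. MCF7, T47D and ZR-75-1 express oestrogen receptor; BT-474 does too and carries an amplified ERBB2 gene. BT-20, MDA-MB-231 and MDA-MB-468 lack oestrogen receptor. Each line was 1 library without replicates, so tests over gene pairs compared these libraries and not kinds of cell line, and intervals covered counting error only. The deposited list held 96 junctions, which joined 150 genes in 86 gene pairs counted per line, or 80 different pairs. A junction was supported by discordant read pairs, whose mates lay in different genes (median 10, range 3 to 1750), and by split reads that crossed it (median 3, range 1 to 156). Discordant pairs were equal over the junctions of a pair in each of the 10 pairs with more than 1, so they look counted per gene pair. The sum of both is called supporting reads, and a pair took its highest value over its junctions. The exons met at annotated boundaries in 95 junctions, the exception being BMP7 to SULF2 in MCF7. Positions are on hg19. Library depth was not part of the list, so the number of pairs in a line could not be scaled to the reads sequenced.

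MCF7 had 32 listed gene pairs, BT-474 18, BT-20 13, ZR-75-1 9, MCF10A 6, and MDA-MB-468 and T47D 4 each. No junction of MDA-MB-231 was among those analysed here, and it was counted as 0. The cancer lines had a mean of 11.4 ± 10.9 pairs (SD, n = 7) against 6 in MCF10A. The difference of 5.43 pairs was within the spread between cancer lines (exact permutation test, two-sided, p = 1, n = 7 and 1). A comparison of 1 line with 7 could not give an exact p below 0.25. Leaving out MDA-MB-231 gave a difference of 7.33 pairs (exact permutation p = 0.857).

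**Figure D1:**
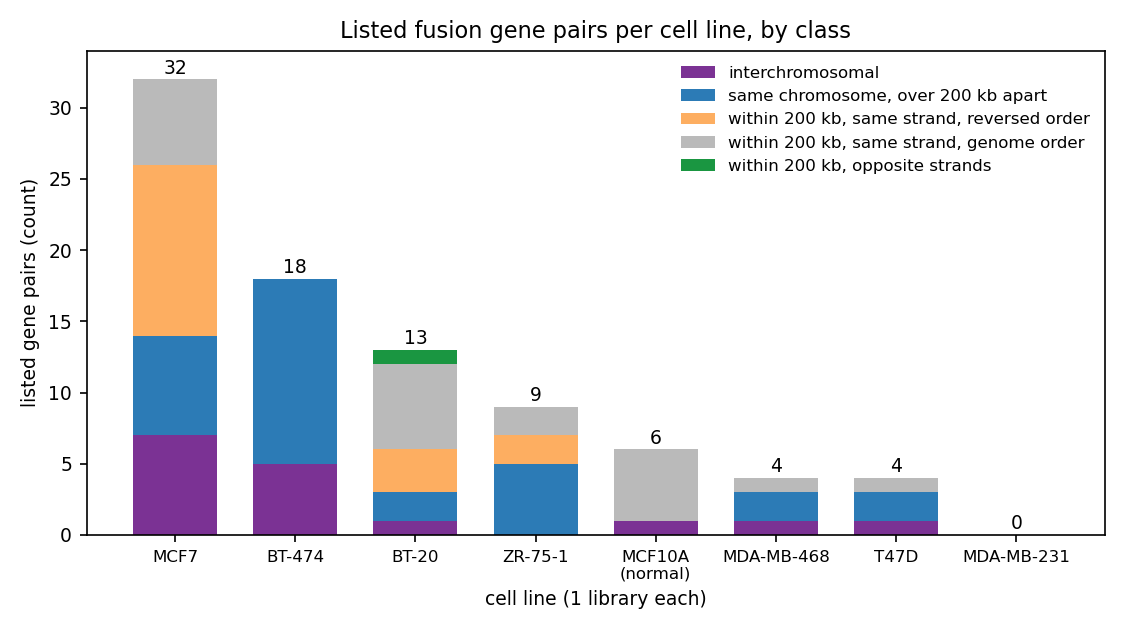
Listed gene pairs (count, vertical axis) in each of the 8 cell lines (horizontal axis, 1 library each), with bar segments for the class of the pair and the total above each bar. MCF7 had 32 pairs and BT-474 18, of which 0 joined genes within 200 kb; 5 of the 6 pairs of MCF10A did so in genome order.

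The fusion with the most reads in MCF7 joined exon 1 of BCAS4 on chromosome 20 (junction at 49411710) to exon 23 of BCAS3 on chromosome 17 (59445688). Both genes were named for amplification in breast cancer, and the junction had 1750 discordant pairs and 55 split reads. The 20 bases on either side read CCCCCGAGCCTGGGGCCGAG and GTACCTTTGACAGGAGCGTG, coding in both genes. ARFGEF2, which activates ARF GTPases at the trans-Golgi, was joined to SULF2, an extracellular sulfatase, with 578 supporting reads. It ran from exon 1 at 47538547 to exon 3 at 46365686 on chromosome 20, through GGCCTGCCAGGTGGCGCTCG and GTTCCATGCAGGTGATGAAC, both coding. RPS6KB1, the S6 kinase downstream of mTOR, was joined to VMP1, a protein of autophagosome formation, with 167 supporting reads. These genes lie on chromosome 17, and their nearest junctions were 72.3 kb apart. TANC2 to CA4, a pair chosen after its value was seen, had 119 supporting reads.

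In BT-474, ZMYND8, a chromatin reader, was joined to CEP250, a centrosome protein, with 200 supporting reads on chromosome 20. RPS6KB1 to SNF8, an ESCRT-II subunit, had 197 reads. It joined exon 1 at 57970686 to exon 2 at 47021337 on chromosome 17. TOB1, an antiproliferative protein, was joined to SYNRG with 122 reads, from the 5′ untranslated region of TOB1 into the coding region of SYNRG. In MDA-MB-468 the pairs with most reads were UBR5 to SLC25A32 (39), ARID1A to MAST2 (25) and FAM76A to MCM4 (8). ARID1A encodes a subunit of the SWI/SNF chromatin remodelling complex and MAST2 a serine/threonine kinase. The ARID1A junction joined coding exon 1 at 27024031 to coding exon 2 of MAST2 at 46290105 on chromosome 1. In ZR-75-1 MINOS1 to RCC2 (74) and C1orf151-NBL1 to RCC2 (73) led, at the same positions on chromosome 1, followed by SREK1 to HOMER1 (30). The first 2 names overlap, so they are 1 event listed under different partner names. BT-20 was led by GOLGB1 to ILDR1 (33), LIMA1 to USP22 (25) and VOPP1 to TYW1 (16). T47D had VPS26A to FAM149B1 (11), ARID3C to DCTN3 (7) and VGLL4 to SH3BP5 (7). MCF10A had ARPC4 to TTLL3 (15), SIDT2 to TAGLN (8) and ZNF783 to LOC155060 (7); these numbers are supporting reads. The median per line ran from 6.5 in MCF10A and 7 in T47D through 10 in BT-20, 14 in ZR-75-1, 16 in MCF7 and 16.5 in MDA-MB-468 to 28 in BT-474. These medians were not tested between lines.

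Fusions known from earlier work on these lines were looked up as a check of the line labels. Of 47 in a list fixed beforehand, 30 were present in the line they are known from: 16 of 26 for MCF7, 12 of 19 for BT-474 and 2 of 2 for MDA-MB-468. Besides BCAS4-BCAS3, ARFGEF2-SULF2 and RPS6KB1-VMP1, MCF7 held SMARCA4-CARM1 (55 supporting reads), RPS6KB1-DIAPH3 (36), ADAMTS19-SLC27A6, GCN1L1-MSI1 and SULF2-PRICKLE2 (32 each). It also held PAPOLA-AK7 (29), DEPDC1B-ELOVL7 (25), ATXN7L3-FAM171A2 (19), TXLNG-SYAP1 (17) and C16orf45-ABCC1 (15). ESR1-C6orf97, which joins the oestrogen receptor gene to the gene now called CCDC170, had 13 reads, and BCAS3-ATXN7 and POP1-MATN2 had 8 each. Besides the pairs with most reads, BT-474 held ACACA-STAC2 (93), VAPB-IKZF3 (88), MED1-STXBP4 (72), STARD3-DOK5 (34) and TRPC4AP-MRPL45 (33). Those with fewer reads were RAB22A-MYO9B (23), PIP4K2B-RAD51C (19), GLB1-CMTM7 (16) and LAMP1-MCF2L (15). ACACA makes malonyl-CoA for fatty acid synthesis and IKZF3 is a zinc finger transcription factor of lymphocytes. Of the 30, ESR1-C6orf97 was the 1 also listed in another line, ZR-75-1. The other 17 known fusions were not in the list.

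Of the 86 pairs, 16 joined different chromosomes, a share of 18.6% (exact Clopper-Pearson 95% interval 11.0% to 28.4%). The share was 21.9% in MCF7 (7 of 32), 27.8% in BT-474 (5 of 18), 7.69% in BT-20 (1 of 13) and 0 of 9 pairs in ZR-75-1 (upper bound 33.6%). MCF10A, MDA-MB-468 and T47D had 1 each, all with a repeated side. That of MCF10A, ZNF283-ARIH2, had a side held by 420 genes, and FAM76A-MCM4 in MDA-MB-468 and T47D had a side held by 131. No difference between lines was detected (permutation test, one-sided, p = 0.629), nor between the cancer lines together, 18.8%, and MCF10A, 16.7% (Fisher's exact test, two-sided, p = 1). Without pairs that have a repeated side the share over all lines was 14.6%.

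Pairs of nearby genes, with junctions at most 200 kb apart on 1 chromosome, made up 39 of 86 pairs, 45.3% (34.6% to 56.5%). BT-474 had none among 18 (upper bound 18.5%), whereas BT-20 had 10 of 13 (76.9%), MCF10A 5 of 6 (83.3%), MCF7 18 of 32 (56.2%) and ZR-75-1 4 of 9 (44.4%). MDA-MB-468 and T47D had 1 of 4 each (25%). The share differed between lines (permutation test, one-sided, p = 1e-05, the smallest that 100000 permutations can give). Without BT-474 the share was 57.4% and the difference between the remaining lines was not past the threshold (permutation p = 0.172). The cancer lines together had 42.5% and MCF10A 83.3% (Fisher's exact test, two-sided, p = 0.0873). With junctions of at least 14.5 supporting reads the share over all lines was 24.4%, below the interval of the full list.

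Nearby pairs fell into different arrangements, a division made after the data were seen. In 21 pairs the exons followed each other in genome order on the same strand, 5.48 to 35.0 kb apart. ARPC4 to TTLL3, SLC39A1 to CRTC2 and SCNN1A to TNFRSF1A were of this kind, as were all 5 nearby pairs of MCF10A. In 17 pairs the downstream gene lay 5′, the reverse of genome order, 51.4 to 159 kb apart: 12 in MCF7, 3 in BT-20 and 2 in ZR-75-1. They included RPS6KB1-VMP1, SMARCA4-CARM1, ESR1-C6orf97, RASSF3-TBK1 and ACTB-RNF216. CIZ1 to LCN2 in BT-20 joined opposite strands. The 31 remaining same-chromosome pairs (36.0%) lay farther apart, up to 22.3 Mb for TRIM37 to MYO19 in BT-474; pairs named here outside the fixed rule were chosen after their values were seen.

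Nearby pairs had fewer reads than the rest, with a median of 8 supporting reads against 25. The mean log2 difference was -1.39 (3.33 ± 1.11, SD, n = 39 pairs, and 4.72 ± 1.84, n = 47), and it was below 0 in 5 of 6 lines. The permutation test of the class within lines gave p = 0.00202 (two-sided; adjusted p = 0.00404 over 4 contrasts), with -0.51 given by the makeup of the lines alone. Reversed pairs such as RPS6KB1-VMP1 had a median of 15 reads and genome-order pairs such as ARPC4-TTLL3 7, a mean log2 difference of 1.37 that was above 0 in 3 of 3 lines (permutation p = 0.00022, adjusted p = 0.00088), with 0.36 given by the makeup of the lines alone. Interchromosomal minus same-chromosome pairs gave 0.36 (permutation p = 0.682, adjusted p = 0.682), though this was below 0 in 4 of 6 lines. Distant same-chromosome minus interchromosomal pairs gave 0.52 (permutation p = 0.461, adjusted p = 0.615), above 0 in 4 of 5 lines. The 0.52 was reversed without repeated sides, as given below. A minimum of 14.5 supporting reads cuts on the compared values themselves; the first difference was then -0.84 (10 and 31 pairs, permutation p = 0.158, adjusted p = 0.475). It left 9 reversed pairs and 1 genome-order pair, with no line holding both, so the reversed-order difference could not be tested. Without MCF7 that difference was 0.72 and no longer past the threshold (permutation p = 0.0478, adjusted p = 0.0955).

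**Figure D2:**
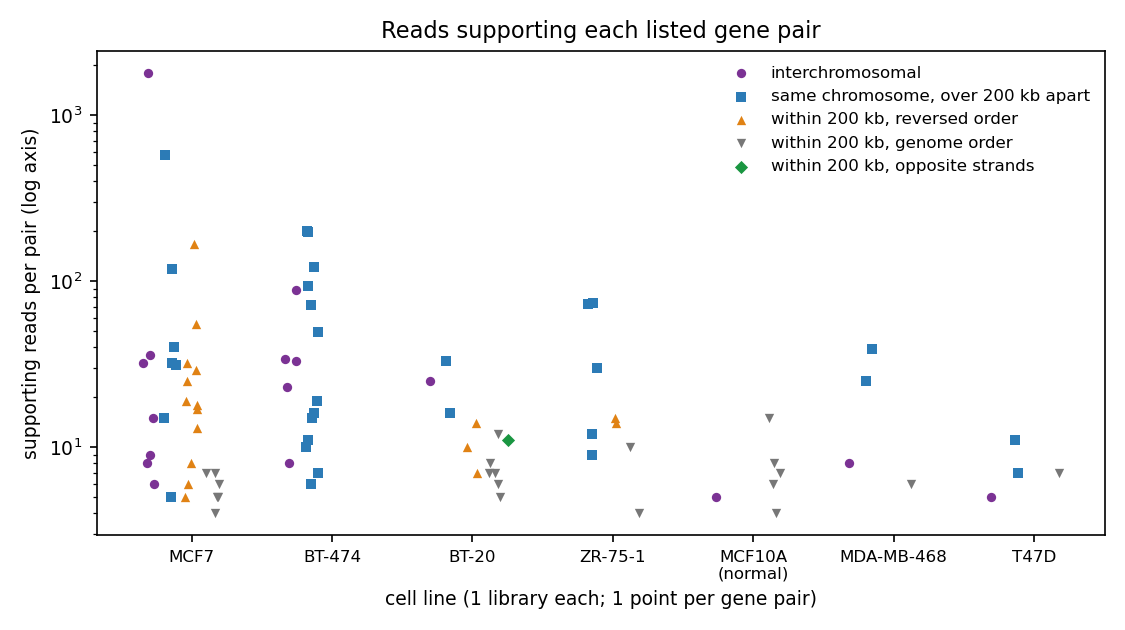
Supporting reads of each gene pair (log axis) by cell line, 1 point per pair, with colour and shape for the class of the pair. The 21 nearby pairs in genome order lie between 4 and 15 reads, while BCAS4-BCAS3 in MCF7 reaches 1805.

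Chromosomes 17 and 20, where BT-474 and MCF7 are known to carry amplified segments, held many of the joined genes. In BT-474, 15 of 36 partner ends lay on chromosome 17 (41.7%) against 13 of 136 in the other lines (9.56%), an odds ratio of 6.76 (Fisher's exact test, two-sided, adjusted p = 0.00207 over 84 tests). Its ends ran from MYO19 at 34.9 Mb to RPS6KB1 at 58.0 Mb. On chromosome 20, 8 of the 36 ends (22.2%) lay between TRPC4AP at 33.7 Mb and VAPB at 57.0 Mb, against 7 of 136 (Fisher's exact test, adjusted p = 0.0635). The adjusted p was 0.0175 with each junction counted, 0.286 with pairs counted and 0.953 with at least 14.5 supporting reads, where the log2 odds ratio was 1.07 against 2.40 in the full list. Of the BT-474 pairs, 12 of 18 touched either chromosome, and VAPB-IKZF3, STARD3-DOK5 and TRPC4AP-MRPL45 joined them. In MCF7, 12 of 32 pairs touched either chromosome, and BCAS4-BCAS3 and TAF4-BRIP1 joined them. Chromosome 1 in ZR-75-1 and chromosome 3 in MCF10A each had an adjusted p of 0.0549. Both passed without high-abundance genes (Fisher's exact test, adjusted p = 0.0383 and 0.0462). In alternatives added after seeing the data, chromosome 1 had an adjusted p of 0.271 with the overlapping names of the RCC2 event counted once and chromosome 3 one of 0.842 without pairs that have an annotated joined sequence. Both ends of a pair are often on 1 chromosome and are not independent: counting pairs instead of ends, a test added after seeing the data, gave 9 of 18 pairs (50%) in BT-474 on chromosome 17 against 10 of 68 (14.7%). The odds ratio of 5.80 was close to that for ends, with Fisher's exact p = 0.00303 and an adjusted p of 0.191. With junctions of at least 14.5 supporting reads the log2 odds ratio for ends was 2.20 against 2.76 in the full list, with an adjusted p of 0.0699.

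**Figure D3:**
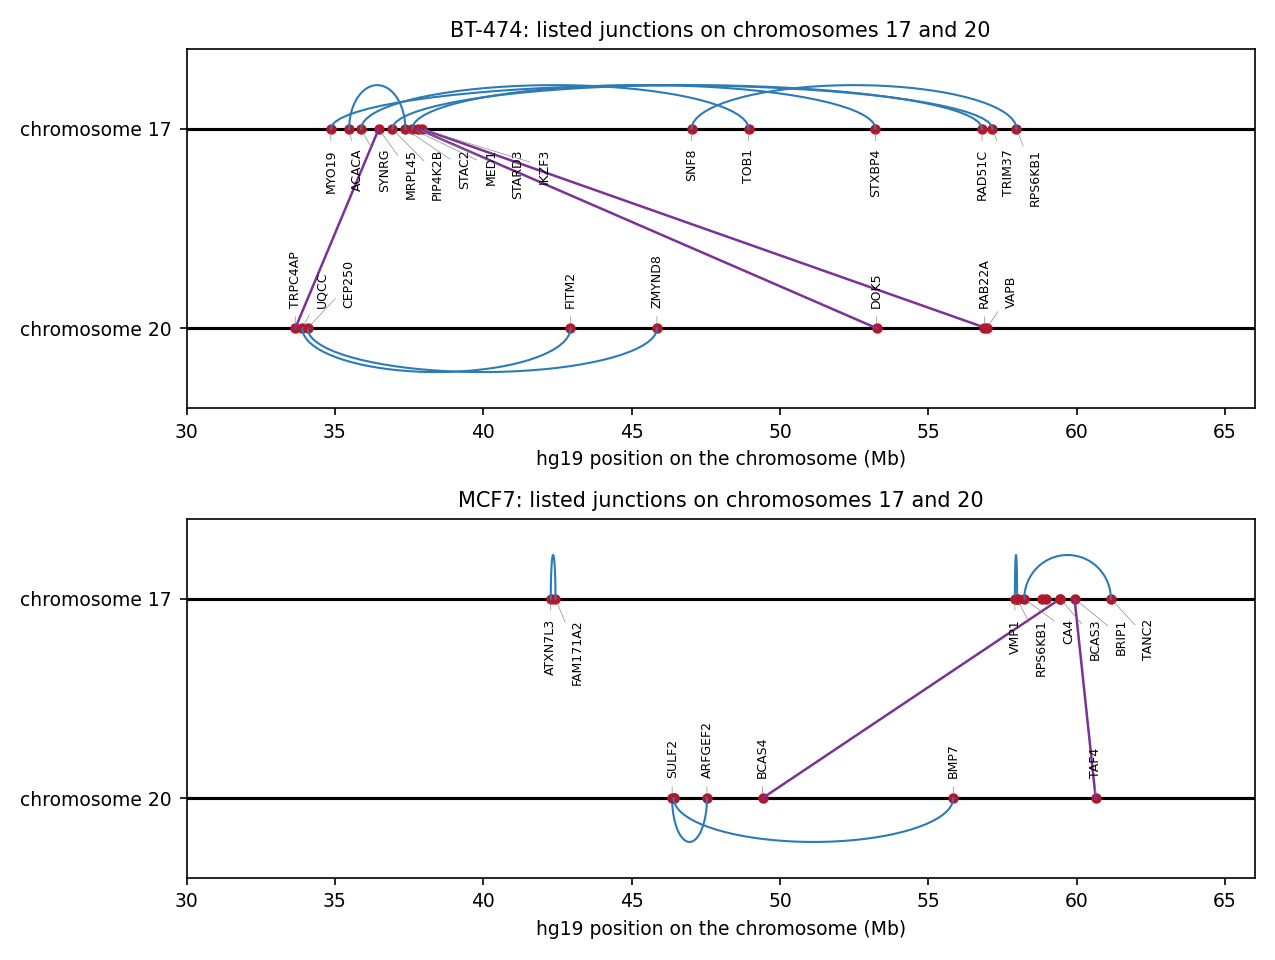
Junction positions (points, hg19, Mb) on chromosomes 17 and 20 in BT-474 and MCF7, with arcs for pairs within a chromosome and straight lines for pairs joining both; each pair is drawn at its junction with most reads. BT-474 has 3 pairs that join the chromosomes and MCF7 has 2.

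Gene groups fixed before the data were examined were compared between interchromosomal and same-chromosome pairs. A list for the 17q12-q23 segment and the ERBB2 amplicon matched 8 of 16 interchromosomal and 7 of 70 same-chromosome pairs (Fisher's exact test, two-sided, adjusted p = 0.00313 over 8 lists). BCAS3, RPS6KB1, IKZF3 and STARD3 were examples of its genes. The list held chosen genes and not every gene of the segment. TANC2-CA4 in MCF7 was not counted, though CA4 lies between RPS6KB1 and BCAS3. A list for the 20q13 segment, with BCAS4, SULF2, VAPB and RAB22A among its genes, matched 7 of 16 against 3 of 70 (Fisher's exact test, adjusted p = 0.00149). It was likewise a chosen set, and its name did not cover all its genes. It counted TRPC4AP, at 33.7 Mb and outside band 20q13. FITM2, which lies between TRPC4AP and SULF2, was not counted. All matched pairs of both lists were in BT-474 and MCF7. Within those lines, Fisher's exact test gave an adjusted p of 0.0122 for 8 of 12 against 7 of 38 pairs and of 0.00548 for 7 of 12 against 3 of 38. Both lists hold partners of fusions known from these lines, so their counts are not independent evidence. A pair matched when either gene was listed, which favours pairs with ends on different chromosomes. The tests cannot tell that from a difference between the classes. BCAS3 in MCF7 gave 4 of the 8 interchromosomal pairs of the 17q list, among them KIAA1324L-BCAS3, which has a repeated side. With junctions of at least 14.5 supporting reads the difference for the 17q list was 36.8 percentage points against 40 in the full list, with an adjusted p of 0.168.

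The other lists held few pairs and had an adjusted p of 1. Breast cancer driver genes were in 3 pairs, ARID1A-MAST2 and ESR1-C6orf97 in MCF7 and ZR-75-1. The list of kinases and transcription factors of recurrent cancer fusions was in 6 pairs, these 3 and RPS6KB1 joined to SNF8, VMP1 and DIAPH3. High-abundance genes were in 3 pairs, ACTB-RNF216, ARL6IP1-RPS15A and FLNB-COL5A2. Luminal markers were in 2 pairs, both ESR1-C6orf97. Basal and mesenchymal markers and HLA or immunoglobulin genes were in 0 pairs.

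Pairs listed in more than 1 line numbered 6, each in 2 lines. ESR1-C6orf97 was in MCF7 (13 supporting reads) and ZR-75-1 (14). Both lines used ESR1 exon 2, in the 5′ untranslated region at 152023140 on chromosome 6, and listed the same junction to C6orf97 at 151894309. ARPC4-TTLL3, which joins an ARP2/3 subunit gene to a tubulin glycylase gene, was in MCF10A (15) and MCF7 (7), and was the 1 pair that the normal line shared with a cancer line. COBRA1-C9orf167 was in BT-20 (12) and MCF7 (5), LOC100131434-IDS in BT-20 (7) and MCF7 (7), and ADCK4-NUMBL in BT-20 (5) and MCF7 (5). The joined sequences of ARPC4-TTLL3 and LOC100131434-IDS are part of annotated transcripts. FAM76A-MCM4, on chromosomes 1 and 8, was in MDA-MB-468 (8) and T47D (5), and its FAM76A side had sequence held by 131 genes. With junctions of at least 14.5 supporting reads ARPC4-TTLL3 was left in MCF10A, and none of the 6 was left in both of its lines.

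Of 150 genes, 6 had more than 1 partner. BCAS3 had 4 in MCF7: BCAS4, REG4, ATXN7 and KIAA1324L, the last through sequence held by 41 genes. RPS6KB1 had 3, SNF8 in BT-474 and VMP1 and DIAPH3 in MCF7, and was the 5′ gene in each. SULF2 had 3 in MCF7: ARFGEF2, BMP7 and PRICKLE2. CIZ1 was joined to FAM102A in BT-474 and LCN2 in BT-20, and MYO9B to RAB22A in BT-474 and FCHO1 in MCF7. RCC2 had 2 overlapping partner names for 1 event.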

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

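The explanations set out for pairs in several lines and for repeated sides were tested after their values were seen, as was the one on sequencing depth in BT-474; those on chromosomes 17 and 20 and on a read minimum in BT-474 were fixed before their tests were run. Some values stood far from the other cancer lines by Dixon's criterion, which chance alone meets in about 1 group of 20 normally distributed values. It was applied to several measures, among them unlogged read numbers, so that rate need not hold here. The highest number of supporting reads in a line was 1805 in MCF7, for BCAS4-BCAS3, against 11 to 200 in the other 5 cancer lines with listed pairs. The median log2 ratio of split reads to discordant pairs was -0.42 in BT-20, against -1.81 to -1.38 in the other cancer lines. It was -0.29 in MCF10A. The median number of discordant pairs was 4 in BT-20 and 3 in MCF10A, while the lowest in the list was 3. These 2 ratios therefore rest on counts near the minimum of the list.

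No nearby pair was listed in BT-474, against 39 of 68 pairs in the other lines together, a line picked for this value (Fisher's exact p = 4.61e-06). A higher minimum of reads in BT-474 did not account for it: among pairs with at least the 4 discordant pairs that BT-474 listed at its lowest, the counts were 0 of 18 and 24 of 50 (Fisher's exact p = 0.000103). Many pairs on chromosomes 17 and 20 filling its list cannot be told apart from a real difference: outside them BT-474 had 0 of 6 nearby pairs and the other lines 37 of 55 (Fisher's exact p = 0.00242), but a list with none gives 0 in any part of it. A lower depth of BT-474 cannot be told apart from a real difference, since depth is not in the list; its other pairs had a median of 28 supporting reads, against 5 to 31.5 in the other lines. The closest BT-474 pair, FAM102A-CIZ1, lay 206 kb apart, the lines still differed at 1 Mb (permutation p = 0.00294), and no biological explanation was tested.

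Pairs listed in 2 lines may hold transcripts that run from one gene into the next without any rearrangement. Of the 6, 4 joined nearby genes in genome order (ADCK4-NUMBL, ARPC4-TTLL3, COBRA1-C9orf167 and LOC100131434-IDS), against 13 of 74 pairs of a single line (Fisher's exact p = 0.0168), as that explanation needs. A transcript spliced in genome order would not give the junction of ESR1-C6orf97, in which the order was reversed in 2 of 2 lines with listed reads. The order alone does not show that the DNA was rearranged. Both lines listed the same junction, to C6orf97 at 151894309 over 129 kb, with 10 discordant pairs and 3 split reads in each. ZR-75-1 also listed a junction at 151914242, over 109 kb. What made that pair in both lines stays open, and a biological explanation was not tested.

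Some interchromosomal pairs may come from reads of 1 gene placed on a repeat in another. In 4 of 18 interchromosomal and 0 of 78 same-chromosome junctions a side was held by more than 10 genes, and these pairs had 5 to 8 supporting reads, against a median of 28.5 in the other 12 interchromosomal pairs. The 60 bases around the junction differed from a transcript of the 3′ partner itself by 0 edits for KIAA1324L-BCAS3, 1 for ZNF283-ARIH2 in MCF10A and 5 for FAM76A-MCM4. In the other 14 interchromosomal junctions the nearest partner transcript was 12 to 15 edits away. A genomic join was not tested, and ZNF283-ARIH2 was the 1 interchromosomal pair of the normal line.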

How the results depend on the processing

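Tests that leave out pairs by sequence, merge names, use 1 kind of read, count pairs per chromosome, leave lines out of the nearby-pair share, or divide pairs by order were chosen after seeing the data. Of 132 comparisons of a main result with an alternative, 117 kept their direction and side of the threshold, or for values without a test stayed within their interval or 1.5 times the main count. Pair numbers kept a p of 0.5 or above, which this design could not bring below 0.25, and known fusions numbered 27 to 30. A minimum of 14.5 supporting reads, the list's own median, left 48 of 96 junctions by definition. MCF7 kept 18 pairs, ZR-75-1 4, BT-20 3, MCF10A 1 and T47D 0, so BT-20 no longer had more pairs than ZR-75-1.

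With at least 14.5 supporting reads the share of nearby pairs was 24.4% and the difference in log2 reads between nearby and other pairs, on which that minimum itself cuts, was -0.84. The reversed-order difference could not be tested, since 1 genome-order pair was left and no line held both kinds. With that minimum 0 chromosome tests passed, 0 pairs were shared between lines, and 1 gene list differed; fewer pairs entered each. Within 1 Mb the share of nearby pairs was 58.1%. Leaving out each line in turn gave shares of nearby pairs of 38.9% to 57.4%, the highest and the 1 lost call without BT-474. It gave interchromosomal shares of 16.2% to 20.8%, nearby-pair read differences of -1.55 to -1.25, reversed-order differences of 0.72 to 1.59, the lowest and the 1 lost call without MCF7 (permutation p = 0.0478, adjusted p = 0.0955), and interchromosomal differences of 0.10 to 0.45. The number of chromosome tests passed was 1 in the main result, 3 without high-abundance genes, 7 with each junction counted, 3 without pairs of several lines, 2 without repeated sides and 0 with pairs counted; the cause was not tested. Each junction counted gave 13 junctions of shared pairs. The ratio of the highest to the lowest median of reads over lines was 4.31, and 6.50 with discordant pairs alone. The latter set 19.5 in BT-474 against 3 in MCF10A, which was the lowest count in the list, and depth was not scaled. The difference of 0.52 between distant and interchromosomal pairs, not past the threshold, was reversed to -0.091 without repeated sides (permutation p = 0.846). That between interchromosomal and same-chromosome pairs, 0.36, was 0.96 there (permutation p = 0.326).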

Other observations

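The tests in this part were chosen after the data were seen. Joined transcripts could be read against coding regions. Over all transcripts of the partners, a junction was called in frame if any combination of them kept the frame. On that most favourable reading, 39 of 96 junctions kept the frame and 34 shifted it. A further 10 joined a 5′ untranslated region to the next gene, as ESR1-C6orf97 and TOB1-SYNRG did. The transcripts expressed in the lines are not known, and VOPP1-TYW1 was out of frame on the listed ones. In-frame joins included RPS6KB1-SNF8 and ACACA-STAC2 in BT-474, ARFGEF2-SULF2, TANC2-CA4 and SMARCA4-CARM1 in MCF7, ARID1A-MAST2 in MDA-MB-468 and LIMA1-USP22 in BT-20. BCAS4-BCAS3 and ZMYND8-CEP250, with the most reads in their lines, shifted the frame.

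On the listed transcripts, 34 of 64 different coding-to-coding junctions were in frame (53.1%). Joining the same partner sides at random gave a mean of 24.0 ± 3.73 (SD over permutations, permutation test, two-sided, p = 0.0122). In-frame junctions were thus more frequent in the list than random pairing gives. The list holds only expressed and called joins, so the test cannot show whether joins were made with regard to frame. Without nearby pairs in genome order the count was 26 of 52 against 19.0 (permutation p = 0.0555), and those pairs alone had 8 of 12 against 6.17 (permutation p = 0.390). Each part held fewer junctions, and neither shows which of them carried the excess. Junctions of 1 pair share a side, and such junctions are not independent.

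The 40 bases across the junction were already part of an annotated transcript for 13 junctions. They made up 12 of 22 junctions of nearby genes in genome order, among them ARPC4-TTLL3, TMEM141-KIAA1984, GXYLT2-PPP4R2 and CNPY2-CS, and 1 of 74 others, KIAA1324L-BCAS3. None of the 19 nearby junctions in reversed order was among them. An annotated transcript joins genes in genome order on 1 strand, so Fisher's exact test of these counts (p = 1.2e-08) had its outcome fixed and decides nothing about the arrangements. In MCF10A 4 of 6 junctions were of this kind, so 2 pairs were left there, SIDT2-TAGLN and ZNF283-ARIH2.

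Known fusions had more reads than the other pairs of the same lines. Medians were 53 against 9 supporting reads in BT-474 (12 and 6 pairs) and 30.5 against 6.5 in MCF7 (16 and 16). In MDA-MB-468 they were 32 against 7 (2 and 2). The mean log2 difference was 2.12 (30 and 24 pairs, permutation within lines, two-sided, p = 2e-05, the smallest these permutations can give). The known fusions found included no nearby pair in genome order and no pair with a repeated side, kinds that had few reads. The other pairs held 6 nearby genome-order pairs in MCF7, and in MDA-MB-468 only GCSH-C16orf46 and FAM76A-MCM4, which are of these kinds. BT-474 listed neither kind. In MCF7 and MDA-MB-468 the difference therefore cannot be told apart from one between kinds of pair. Earlier work may also have found the fusions with most RNA first, which was not tested.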
